A study of Homo sapiens with 2 samples.

How the data were processed

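MicroRNAs (miRNAs) were measured by small-RNA sequencing in 2 libraries, 1 from each of 2 human breast cancer cell lines. Per the labels' protocols, stem-enriched subpopulations of MDA-MB-468 and BT474 were sorted with CD24 and CD44 by flow cytometry, and total RNA was isolated with Trizol. Adaptors were ligated to the 3' and then the 5' ends, cDNA was amplified by PCR, and fragments of 135 to 155 bp, corresponding to small RNAs of 15 to 35 nt, were selected and read for 51 cycles on an Illumina HiSeq. Groups were taken from the cell line stated in the sample labels. A column header that spells the line MAD-MB-468 was read as MDA-MB-468, the only title it resembles.

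The authors deposited raw tag counts and a normalized version of the same table. Per the file headers, a raw value is the count of all isoform tags of a mature miRNA on a given precursor, so a tag that matches several precursors is listed under each. In the deposited table the smallest listed count was 2 in both libraries and other cells were blank, so a blank is a value that was not listed and not a measured 0. The deposited normalized values are scores that the authors rounded to whole numbers; their columns sum to 988744 for MDA-MB-468 and 985422 for BT474. The scaling behind these scores is not described in the file headers. Novoalign 2.07.11 is named in the submitters' processing notes. The genome build, the miRNA annotation release and the counting tool are not given in the sources used here.

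The raw table held 2121 rows, of which 384 were predicted hairpin candidates without an established miRNA name and 1737 were annotated. The annotated rows carried 1624 mature names, 85 of them on several precursors. The counts of such a name differed slightly between its precursors, so the largest was kept, in place of the planned collapse of rows with equal counts. The names miR-199a-3p and miR-199b-3p had equal counts throughout and were merged, which left 1623 mature miRNAs. Names with nearly equal counts, such as miR-365a-3p and miR-365b-3p (2251 and 2253 in MDA-MB-468), were not merged. Tags they share enter the totals and the counts of calls under each name. The predicted candidates stayed out of the totals and the comparisons, a choice made after the files were seen, and an alternative includes them.

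Counts were scaled to counts-per-million (CPM) of the total over annotated miRNAs, 11448022 in MDA-MB-468 and 5133057 in BT474. Ratios are MDA-MB-468 over BT474. With 1 library per group no test of the groups is possible, so each ratio has an exact conditional binomial (Clopper-Pearson) interval at the 95% level. Shares of counts have exact Clopper-Pearson intervals, and CPM values exact Poisson intervals. PCR reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only and say nothing of the spread between cultures. In ratios a blank was set at a floor of 3 counts, which is 0.262 CPM in MDA-MB-468 and 0.584 CPM in BT474. A miRNA was eligible with at least 10 counts in at least 1 library, which held for 690, and 90 of these were blank in BT474 and 46 in MDA-MB-468. It was called higher or lower where the ratio reached 2-fold in either direction and its interval excluded 1. The floor entered the ratio alone, and the interval took a blank as 0 counts. Calls of miRNAs blank in 1 library are therefore less cautious than the floor, and no interval was computed at the floor.

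Before the data were examined, 22 lists of miRNAs were fixed: families, genomic clusters, breast cancer subtype lists and markers of other cell types. For each list with at least 3 eligible members, the median log2 ratio was placed as a percentile among 10000 random lists of the same size, matched on mean log2 CPM in 5 bins. A list stood apart in the outer 5%, counted over both tails together. Arms of 1 hairpin and members of 1 cluster are not independent, so a percentile describes these libraries and is not a test. Members were matched by name without the arm, so member counts mix both arms of a hairpin. A target or function given for a list need not hold for both arms. The arm preference of a hairpin is the share of 5p reads among its 5p and 3p reads, taken for hairpins with at least 100 reads in each library whose arm names are each listed on 1 precursor. Hairpins whose arms carry different names can still share reads, as mir-365a and mir-365b, with 2251 and 2253 reads of the 3p arm in MDA-MB-468; neither shifted. A shift means a difference of at least 20 percentage points with intervals that do not overlap.

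The miRNAs named in the report follow a rule fixed in advance: the 5 most abundant per library, the 10 highest and 10 lowest ratios among the 185 miRNAs with at least 100 CPM in at least 1 library, up to 4 members of each list, the hairpins with an arm shift, and miR-4728, miR-21, miR-221, miR-222, miR-205, miR-375, miR-190b and miR-210. Other miRNAs named were chosen after their values were seen. Positions come from GENCODE 29 on GRCh38, matched by gene name for 1084 of 1087 precursors; they are the coordinates of that annotation and not of the authors' files.

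Alternatives covered the scaling (edgeR's TMM, DESeq2's size factors, the upper quartile, the authors' normalized values, and the total without the 10 most abundant miRNAs of either library), 0.5 added to every count, other count minimums and folds, thinning of the deeper library, and unmatched random lists. With the authors' normalized values no interval was computed, so a call there rested on the 2-fold ratio alone. Alternatives with the predicted candidates in the totals and with the more abundant arm of each hairpin alone were added after the data were seen. The ratio rule was tested on simulated counts with 200 planted changes, and 678 simulated miRNAs were eligible, 143 with a planted change and 535 without. Intervals covered 96.2% of their true ratios, 84.6% of the eligible 3-fold and 87.2% of the eligible 8-fold changes were called in the right direction, and 7 unchanged miRNAs (1.31%) were called. Simulated lists held 10 members with independent log2 ratios of standard deviation 2. Of 200 such lists without a shift, 3% stood apart, and 48 of 50 lists with every member shifted by 3 were found. Members of the real lists are not independent and most list medians were smaller than that shift, so neither rate need hold for them. The work used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0 for scaling factors alone.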

Results

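Small RNAs were sequenced from stem-enriched subpopulations of 2 breast cancer cell lines to compare the miRNA pattern of the 2 cell types. MDA-MB-468 is a triple-negative line, described in the labels as lacking the oestrogen receptor (ER), the progesterone receptor and HER2, and BT474 is described as ER-positive. CD24 and CD44, the surface proteins used for the sort, are common markers for enriching breast cancer stem cells. Each group held 1 library, so no difference below has a replicate check, and each error is a 95% interval for counting error between these libraries. Unsorted cells of either line were not analysed here and the lines were grown in different media, so cell line, sort and medium cannot be separated. The MDA-MB-468 library held 11448022 counts of annotated miRNAs and the BT474 library 5133057, with 603 and 506 miRNAs at 10 counts or more. At these depths 100 counts corresponded to 8.74 CPM in MDA-MB-468 and 19.5 CPM in BT474.

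The composition of each library was examined first. miR-21-5p, a widely described oncogenic miRNA, was the most abundant in both and took 54.2% of BT474 counts (Clopper-Pearson interval 54.2 to 54.3) against 25.1% of MDA-MB-468 counts (25.1 to 25.2). In MDA-MB-468 it was followed by miR-148a-3p with 17.02%, miR-30a-5p with 6.91%, miR-200b-3p with 5.05% and let-7i-5p with 4.66%. In BT474 the next were let-7i-5p with 4.55%, let-7f-5p with 4.29%, miR-200c-3p with 2.66% and miR-7-5p with 2.53%. The 10 most abundant miRNAs held 71.7% of the MDA-MB-468 library and 78.0% of the BT474 library.

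**Figure D1:**
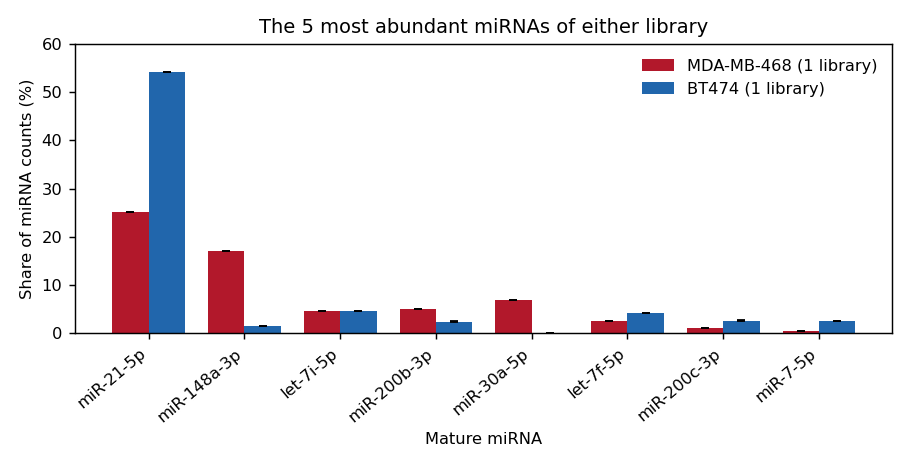
Share of annotated miRNA counts, in percent, of each miRNA among the 5 most abundant of either library, with MDA-MB-468 in red and BT474 in blue (1 library each) and exact Clopper-Pearson 95% intervals as error bars. miR-21-5p took 54.2% of the BT474 library and 25.1% of the MDA-MB-468 library, and miR-148a-3p 17.02% of the latter.

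The question of the study was which miRNAs differ between the triple-negative and the ER-positive stem-enriched cells. The highest ratios among abundant miRNAs belonged to miR-934 (949 CPM in MDA-MB-468 and 1.56 in BT474, log2 ratio 9.25, interval 8.27 to 10.46) and miR-767-5p (229 and 0.390 CPM, 9.20, 7.35 to 12.25, but 7.65 with the authors' normalized values). miR-205-5p, a miRNA of basal epithelial cells, reached 14367 CPM in MDA-MB-468 and 61.6 in BT474, a 233-fold difference (log2 7.87, 7.71 to 8.03); if 239 of its 316 BT474 counts, the most that the counts of miR-934 allow, were carried over from the other library, the fold would be 955.5. miR-30a-5p was 129-fold higher in MDA-MB-468, at 69072 against 534 CPM (log2 7.02, 6.96 to 7.07). miR-148a-3p, which targets the DNA methyltransferase DNMT1, was not among the 10 highest ratios but was 11.4-fold higher in MDA-MB-468, at 170240 against 14990 CPM (log2 3.51, 3.50 to 3.52). The other miRNAs among the 10 highest ratios were miR-181a-2-3p (log2 7.16), miR-135b-5p (7.12), miR-30a-3p (6.21), miR-30c-2-3p (6.19, and 7.37 with the authors' normalized values), miR-130a-3p (6.07) and miR-584-5p (5.61). The BT474 counts behind these ratios were low for miR-767-5p (2 counts), miR-181a-2-3p (6), miR-934 (8) and miR-130a-3p (8).

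In the other direction, miR-653-5p had 2 counts (0.175 CPM) in MDA-MB-468 and 536 CPM in BT474, a log2 ratio of -11.58 (-14.63 to -9.73, but -8.80 with the authors' normalized values). miR-296-3p had 0.437 against 404 CPM (log2 -9.85, -11.48 to -8.63, but -8.37 with the same values). miR-708-5p and miR-504-5p were not listed in MDA-MB-468 and had 224 and 191 CPM in BT474, at least 856-fold and 730-fold higher with the blank set at 3 counts (log2 -9.74 and -9.51). These figures rest on the value given to the blank: the log2 ratios were -7.52 and -7.30 with the authors' normalized values, whose blanks were set at the smallest listed value. miR-152-3p, which shares its seed with miR-148a-3p, was 12.3-fold higher in BT474 (82.2 against 1014 CPM, log2 -3.62, -3.73 to -3.52). miR-149-5p was 8.11-fold higher in BT474 (120 against 972 CPM). The list of the 10 lowest ratios was completed by miR-1275 (log2 -4.10), miR-625-3p (-4.03), miR-195-5p (-2.93) and miR-25-5p (-2.79). miR-21-5p itself was 2.16-fold higher in BT474 (251480 against 542430 CPM, log2 -1.11, -1.11 to -1.11), and its passenger arm miR-21-3p had a log2 ratio of -1.61 (-1.65 to -1.56).

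Several of these hairpins lie inside protein-coding genes (GENCODE 29, GRCh38). MIR934 lies in an intron of VGLL1 (chromosome X, 136550878 to 136550960), MIR767 in an intron of GABRA3 (chromosome X, 152393421 to 152393529) and MIR135B in an intron of LEMD1 (chromosome 1, 205448302 to 205448398). MIR205 overlaps an exon of its host transcript MIR205HG (chromosome 1, 209432133 to 209432242). Of those higher in BT474, MIR653 lies in an intron of CALCR, the calcitonin receptor gene (chromosome 7, 93482760 to 93482855), MIR708 in an intron of TENM4 (chromosome 11, 79402022 to 79402109) and MIR504 in an intron of FGF13 (chromosome X, 138667711 to 138667793). MIR152 lies in an intron of COPZ2 (chromosome 17, 48037161 to 48037247), and MIR21 overlaps an exon of VMP1 (chromosome 17, 59841266 to 59841337).

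**Figure D2:**
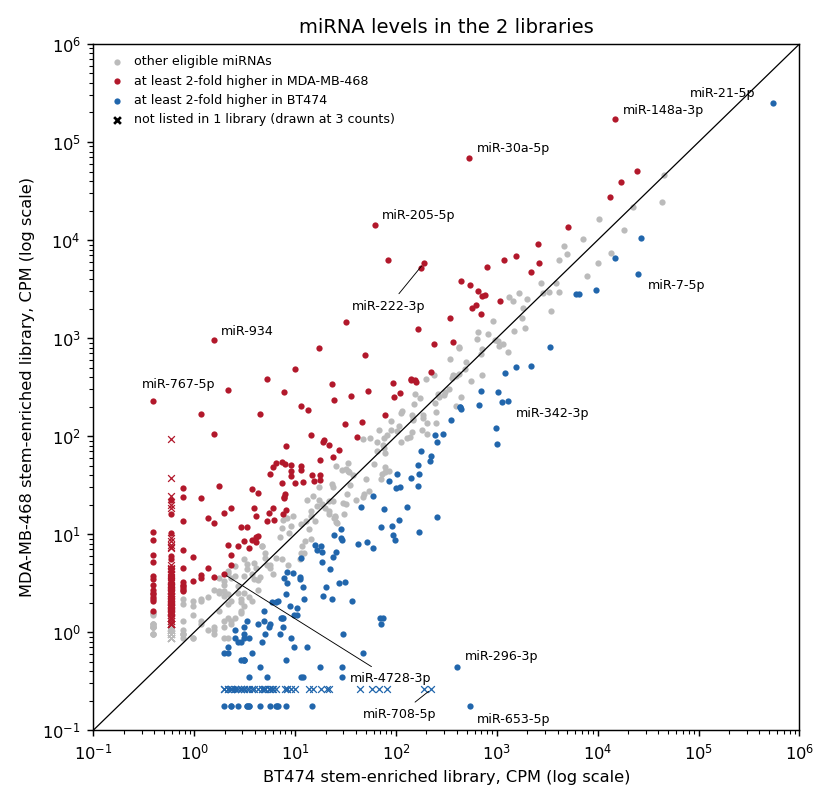
CPM of each of the 690 eligible miRNAs in the BT474 library (horizontal log axis) and the MDA-MB-468 library (vertical log axis), 1 library each, with the line of equal CPM. Red points were called at least 2-fold higher in MDA-MB-468 (227), blue points at least 2-fold higher in BT474 (195) and grey points neither (268); crosses mark miRNAs not listed in 1 library, drawn at 3 counts.

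Of the 690 eligible miRNAs, 227 were called higher in MDA-MB-468, 195 higher in BT474 and 268 neither, which describes these libraries and is not a test of the cell types. The median log2 ratio over all eligible miRNAs was 0.30, and 0.03 with the deeper library thinned to the depth of the other. That thinning gave 197 higher in MDA-MB-468 and 195 higher in BT474. Scaling to the total without the 10 most abundant miRNAs moved all log2 ratios by -0.38 and gave 177 higher in MDA-MB-468 and 239 higher in BT474, and upper-quartile scaling moved them by -0.21 and gave 196 and 222. DESeq2's size factors moved them by -0.12 and gave 208 and 209.

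The preset lists were then compared, and 4 of them stood apart from matched random lists. Basal-like breast miRNAs, described as higher in ER-negative lines, had 12 of 17 eligible members called higher in MDA-MB-468 and 1 lower, with a median log2 ratio of 3.62 (percentile 100). The median member was miR-205-3p, blank in BT474 and set at 3 counts. Within the list, miR-221-3p and miR-222-3p, which target the ER transcript ESR1 and the cell-cycle inhibitor CDKN1B, were 29.5-fold and 30.7-fold higher (log2 4.88, 4.79 to 4.98, and 4.94, 4.85 to 5.04), and miR-221-5p had a log2 ratio of 5.54. miR-222-5p was at least 42.0-fold higher with its BT474 blank set at 3 counts (log2 5.39, and 4.32 with the authors' normalized values). The member called lower was miR-155-5p (log2 -1.26, -1.54 to -0.99), while miR-9-5p (-0.98) and miR-146a-5p (0.76) were not called.

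The miR-30 family had 9 of 11 members called higher in MDA-MB-468 and 1 lower, with a median of 2.16 (percentile 99.9). Besides miR-30a, its members miR-30c-5p (log2 2.16, 2.12 to 2.19) and miR-30d-5p (1.20, 1.19 to 1.21) were called higher, the latter not under 2 of 7 alternatives. The miR-17/92 cluster and its paralogs, induced by MYC and E2F, had 15 of 24 members called higher and 3 lower, with a median of 1.78 (percentile 99.97; 96.4 from the authors' normalized values, which is inside the middle range). miR-20a-5p was 5.31-fold higher in MDA-MB-468 (log2 2.41, 2.37 to 2.45) and miR-92a-3p 2.65-fold (1.41, 1.39 to 1.43), whereas miR-25-3p, of the paralogous cluster on chromosome 7, was 2.26-fold higher in BT474 (log2 -1.18, -1.19 to -1.16) and miR-93-5p was at -0.16. The miR-29 family, which represses collagen genes, had 5 of 7 members called higher and none lower, with a median of 1.90 (percentile 97.4, just inside the middle range, and in the outer 5% under 2 alternatives). Its members miR-29a-3p and miR-29b-3p had log2 ratios of 2.89 and 1.90.

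The list of ERBB2 and 17q miRNAs stood apart in the other direction. Of its 16 members 9 were called lower in MDA-MB-468 and 4 higher, with a median of -1.07 (percentile 1.37). miR-454-3p was 5.05-fold higher in BT474 (log2 -2.34, -2.40 to -2.27), beside miR-21-5p, miR-21-3p and miR-152-3p above. The list lost its place in the outer 5% against unmatched random lists (2.79) and with the more abundant arm of each hairpin alone (4.43). miR-4728-3p, encoded in an intron of ERBB2 (MIR4728, chromosome 17, 39726495 to 39726561), had 45 counts in MDA-MB-468 and 10 in BT474, or 3.93 and 1.95 CPM. Its log2 ratio of 1.01 (0.00 to 2.17) lost its call in 6 of 7 alternatives. The call was kept only with the authors' normalized values, for which no interval was computed. The other members called higher in MDA-MB-468 were miR-10a-5p (1.29), not under 1 of 7 alternatives, miR-196a-5p (3.26) and miR-196a-3p, which are transcribed from HOX clusters. The miR-196a hairpins lie on chromosome 17 (MIR196A1) and on chromosome 12 (MIR196A2). Counts of the miR-196a names therefore need not come from 17q.

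Luminal breast miRNAs, described as higher in ER-positive disease, were divided: 7 of 19 members were called lower in MDA-MB-468, 6 higher and 6 neither, with a median of -0.57 (percentile 6.395). miR-7-5p, which targets EGFR, was 5.65-fold higher in BT474 (log2 -2.50, -2.51 to -2.48), and miR-342-3p was 5.71-fold higher (-2.51, -2.58 to -2.45). miR-26a-5p (-0.78), miR-375 (-0.32) and miR-203a-3p (-0.85) were not called. The members higher in MDA-MB-468 included both arms of miR-30a and miR-190b, the latter at 7.25 against 3.51 CPM (log2 1.05, 0.30 to 1.87), whose call was lost in 3 of 7 alternatives.

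Lists of epithelial, differentiation-linked and cell-cycle miRNAs did not stand apart from matched random lists. The miR-200 family, which represses ZEB1 and ZEB2, had 2 of 9 members called higher in MDA-MB-468 and 2 lower, with a median of 0.54 (percentile 72.6, but 42.0 with at least 50 counts). miR-200b-3p was 2.05-fold higher in MDA-MB-468 (log2 1.04, 1.03 to 1.05), a call lost in 3 of 7 alternatives, and miR-200c-3p was 2.55-fold higher in BT474 (log2 -1.35, -1.36 to -1.34). miR-200a-3p (0.54) and miR-429 (0.80) were not called. The let-7 family had 15 of 19 members not called, 2 higher and 2 lower, with a median of 0.00 (percentile 36.6) whose sign depended on the scaling. let-7i-5p stood at 46553 CPM in MDA-MB-468 and 45539 in BT474 and let-7g-5p at 21785 and 22258, whereas let-7a-5p (log2 -0.88) and let-7f-5p (-0.80) reached 2-fold under 3 and 2 of 7 alternatives. The cluster of miR-183, miR-96 and miR-182 had 2 of 5 members lower in MDA-MB-468 and 3 not called (median -0.88, percentile 10.5, but 19.05 with the more abundant arm alone), with miR-182-5p at -0.53 and miR-183-5p at -0.88. The miR-15/16 family had 5 of 12 lower and 7 not called (median -0.91, percentile 3.43, but 6.74 against unmatched random lists), with miR-16-5p at -0.02 and miR-15b-5p at -0.02.

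Of the remaining clusters, the imprinted C14MC cluster had all 7 eligible members lower in MDA-MB-468, with a median of -3.48 (percentile 2.60, just inside the middle range, in the outer 5% under 3 alternatives and at 6.28 without a count minimum). Its members were scarce, 4 of them, the median member included, being blank in MDA-MB-468 and set at 3 counts: miR-381-3p had 2.18 CPM in MDA-MB-468 and 23.2 in BT474 (log2 -3.41, -4.09 to -2.78), and miR-323a-3p was not listed in MDA-MB-468 and had 4.29 CPM in BT474. The C19MC cluster, expressed in placenta, had 6 of 7 members higher in MDA-MB-468, with a median of 1.51. Its percentile was 85.2, but 8.83 without a count minimum and 51.98 with the authors' normalized values. The median member miR-516b-5p and also miR-519a-5p (log2 2.12) were blank in BT474 and set at 3 counts. Both were at 0 with the authors' normalized values and lost the call there. The cluster was led by miR-522-3p with 31 counts against 2 (log2 2.80, but 1.00 with the authors' normalized values). The miR-181 family had 4 of 8 higher and none lower (median 1.18, percentile 94.5, but 68.46 with the more abundant arm alone), with miR-181a-3p at 3.77 and miR-181b-5p at 0.02. HOX-embedded miRNAs had 4 of 7 higher and 1 lower (median 1.29, percentile 91.1); miR-615-3p was at 1.42 and miR-196b-5p at -2.59. The miR-23/27/24 clusters had 5 of 11 higher and 1 lower (median 0.95, percentile 91.6), and miR-27b-3p (1.06) and miR-23a-3p (1.11) each lost the call in 3 of 7 alternatives. The clusters of let-7c, miR-99, miR-100 and miR-125 had 4 of 13 higher and 2 lower (median 0.63, percentile 79.6), with miR-99a-5p at 1.17, a call lost in 2 of 7 alternatives, and miR-125a-5p at -1.12. p53-induced miRNAs had 2 of 7 higher and 1 lower (median 0.78, percentile 75.8), with miR-192-5p at 1.79 and miR-34a-5p at 0.79.

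Markers of other cell types did not stand apart either. Mesenchymal and stromal markers had 2 of 5 members higher in MDA-MB-468 and 1 lower, with a median of 0.27 (percentile 63.1) that turned negative with the total without the 10 most abundant miRNAs. Of these, miR-143-3p reached 354 CPM in MDA-MB-468 and 158 in BT474 (log2 1.17) and miR-145-5p 13.98 and 6.23 CPM, both calls being lost in 2 of 7 alternatives. Blood cell markers had 3 of 5 lower in MDA-MB-468 (median -1.02, percentile 22.3, but 68.2 without a count minimum), and miR-142-3p was at 7.69 and 15.8 CPM. Of the muscle, liver and neuron markers, miR-1-3p alone was eligible, at 1.31 and 4.87 CPM, and no miRNA of the pluripotency list reached 10 counts in either library. The hypoxia-induced miR-210-3p was at 266 CPM in MDA-MB-468 and 259 in BT474 (log2 0.04, -0.05 to 0.14), and miR-210-5p at 3.67 and 4.48 CPM.

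**Figure D3:**
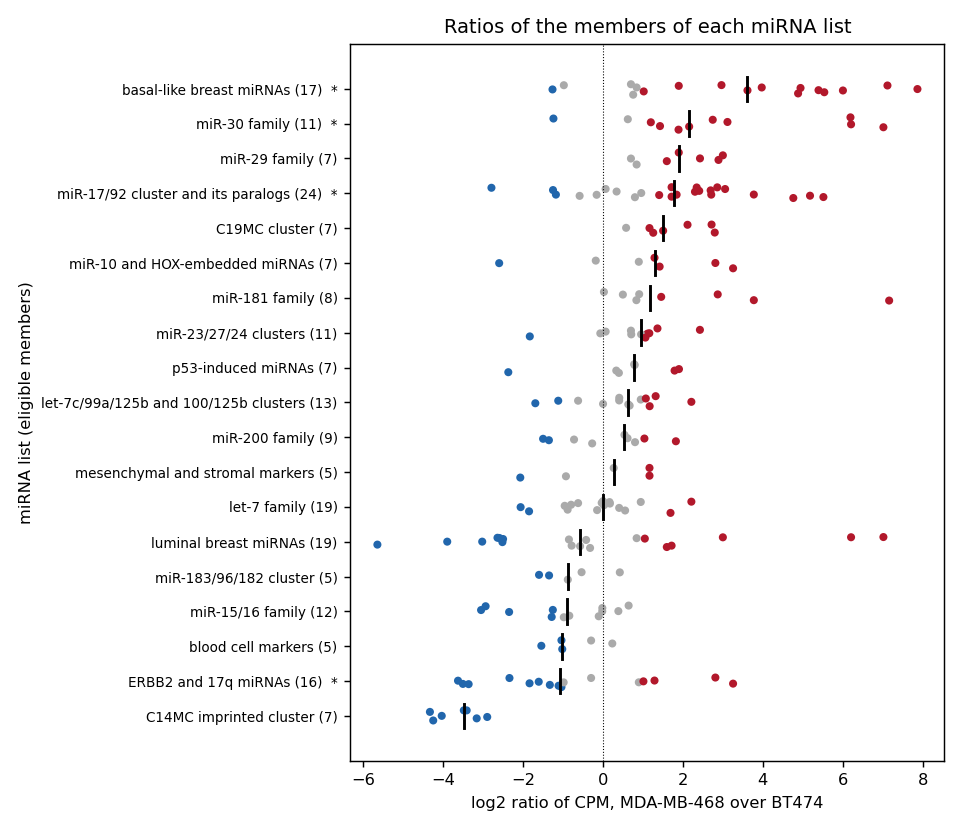
Log2 ratio of CPM, MDA-MB-468 over BT474 (horizontal axis), of each eligible member (points) of each preset list with at least 3 such members (vertical axis, number of members in brackets), with a black bar at the list's median. Red points were called at least 2-fold higher in MDA-MB-468, blue points at least 2-fold higher in BT474 and grey points neither; an asterisk marks the 4 lists in the outer 5% of matched random lists, 3 to the right (medians 3.62, 2.16 and 1.78) and 1 to the left (-1.07).

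Arm preference, which does not depend on scaling, was compared for 124 hairpins. The share of 5p reads shifted in 4 of them. It was 57.6% in MDA-MB-468 (interval 56.3 to 59.0) and 90.6% in BT474 (88.1 to 92.8) for mir-877, and 60.9% (59.4 to 62.4) and 84.3% (82.3 to 86.1) for mir-574. For mir-671 it was 32.8% (30.9 to 34.7) and 54.4% (52.0 to 56.9). For mir-339 the direction was the opposite, with 74.6% (72.8 to 76.3) in MDA-MB-468 and 45.9% (43.8 to 48.1) in BT474. In 99 of the 124 hairpins the shares lay within 5 points of each other, and the median difference was 0.695 points.

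The authors' normalized values were compared with the raw counts across miRNAs, which are not independent replicates. Among values above 500, 1 normalized unit corresponded to 12.9 to 13.3 counts in MDA-MB-468 (109 rows) and to 6.07 to 6.23 counts in BT474 (94 rows). On the log2 scale Pearson's correlation was 0.995 in each library, and Spearman's was 0.988 in MDA-MB-468 and 0.990 in BT474. Blank cells were more frequent in the normalized table, by 576 rows in MDA-MB-468 and 413 in BT474, and the largest raw count behind such a blank was 29 and 21.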

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

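The tests of miR-4728-3p and of carried-over reads in this part were chosen after the results were seen. Predicted hairpin candidates, which no comparison used, made up 3.53% of all listed counts in MDA-MB-468 and 2.92% in BT474, a signal outside the measurement reported above. Of the 191 candidates with at least 10 counts in a library, 62 were called higher in MDA-MB-468 and 62 higher in BT474. The largest count of a candidate was 95198 in MDA-MB-468 and 31637 in BT474, each taken within its library and not necessarily from the same candidate.

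miR-4728-3p, encoded in an ERBB2 intron, was not higher in BT474 (1.95 CPM against 3.93 in MDA-MB-468), although BT474 is widely known as a line with amplified ERBB2. An exchange of the 2 libraries would put the basal-like list below 0 in the MDA-MB-468 over BT474 ratio, but its median log2 ratio was 3.62, so the tables argue against an exchange. Counting noise could hide a 2-fold higher BT474 level only if the upper 95% limit of the BT474 over MDA-MB-468 ratio reached 2, and it was 0.998, with 1.30 the highest over the scalings tried. Poor capture of this miRNA in both libraries cannot be told apart from a truly low level, because the libraries held 55 counts together and no other measure of miR-4728 or ERBB2 was analysed here. A difference between the lines or the sorted subpopulations also stays open and was not tested.

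miRNAs abundant in MDA-MB-468 had small counts in BT474, such as the 316 counts of miR-205-5p against 164474, and reads carried over from the other library are a candidate source. The test took the 62 miRNAs called higher in MDA-MB-468 with at least 1000 counts there. miR-934, with 8 counts against 10860, had the smallest upper limit among them and bounds such carry-over at 0.145%. By their lower 95% limit 58 of the 62 (93.5%) exceeded the bound, which for each of the 58 argues against carry-over as the whole source of its BT474 counts. Many were well counted in both libraries, such as miR-200b-3p with a share of 21.8%, and could hardly lie under the bound. The 93.5% therefore says little about miRNAs with small BT474 counts. For miR-205-5p the share was 0.192% (0.171 to 0.215), and the bound would allow 239 of its 316 counts, which would raise its fold from 233 to 955.5. The other 4 of the 62 miRNAs (miR-105-5p, miR-934, miR-767-5p and miR-181a-2-3p) did not exceed the bound by their lower 95% limits. Of these, miR-934 set the bound and miR-105-5p was not listed in BT474, so neither could exceed it. For miR-934, miR-767-5p and miR-181a-2-3p carry-over and a low true level cannot be told apart. The share of miR-181a-2-3p was 0.314% (0.115 to 0.684). Expression differences between the lines stay open as the source of the counts above the bound and were not tested separately.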

How the results depend on the processing

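No paired analysis was possible because each group held 1 library, and for the same reason no library could be left out. Alternatives with the predicted candidates in the totals and with the more abundant arm alone were chosen after the data were seen. Of 107 named miRNAs under 7 alternatives (749 values), 42 calls changed in 19 miRNAs: 30 were lost, 12 gained and none reversed. Of the 74 called, 61 kept the call under all 7, and 13 lost it in at least 1. miR-4728-3p lost it in 6, and its log2 ratios over all 7 ranged from 0.63 to 1.58. The highest came from the authors' normalized values, where a call rested on the ratio alone, without an interval.

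The median log2 ratio of all eligible miRNAs, 0.30 in the main scaling, was 0.095 with the upper quartile, 0 with the authors' normalized values, which list fewer miRNAs, 0.03 with the deeper library thinned to the depth of the other, and -0.077 with the total without the 10 most abundant miRNAs. Requiring 50 counts reduced the calls to 146 higher in MDA-MB-468 and 103 higher in BT474 by testing fewer miRNAs, and a 4-fold rule left 123 higher in MDA-MB-468 and 131 higher in BT474; the other alternatives gave 177 to 279 higher in MDA-MB-468, and 183 to 241 higher in BT474. The miR-17/92 list moved to percentile 96.38 with the authors' normalized values, and the ERBB2 and 17q list to 2.79 against unmatched random lists and 4.43 with the more abundant arm alone; the cause was not tested. Scalings that move all log2 ratios by 1 constant cannot change a list's percentile. Those are TMM, DESeq2's size factors, the upper quartile and the totals without the 10 most abundant miRNAs or with predicted candidates. Under the other alternatives the basal-like and miR-30 lists stayed in the outer 5%. The C14MC list entered the outer 5% under 3 of them and the miR-29 list under 2. The luminal list ranged from 3.74 with 50 counts required to 10.36 without a count minimum, inside the middle range throughout. The more abundant arm alone moved the miR-181 list from 94.5 to 68.46 and the list of let-7c, miR-99, miR-100 and miR-125 from 79.6 to 61.78. With 50 counts required, the C14MC and C19MC lists had fewer than 3 members and no percentile. Without a count minimum the C14MC list moved from percentile 2.60 to 6.28, the C19MC list from 85.2 to 8.83 and the blood cell markers from 22.3 to 68.2, and the authors' normalized values moved the stromal markers from 63.1 to 33.2; the cause was not tested. With repeated rows left in, miR-21-5p took 23.28% of MDA-MB-468 and 47.77% of BT474, and 22.45% and 46.38% with the predicted candidates too, since both enlarge the total. A minimum of 30 reads per hairpin gave 8 arm shifts, by testing more hairpins, and 500 reads gave 4. Depth limits ratios of scarce miRNAs: 3 counts were 0.262 CPM in MDA-MB-468 and 0.584 CPM in BT474.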

Other observations

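The comparison of neighbouring hairpins in this part was chosen after its result was seen, and the miRNAs and clusters named here after their values were seen. The hairpins of miR-653-5p and miR-489-3p lie together in an intron of CALCR, and both were higher in BT474: miR-489-3p was not listed in MDA-MB-468 and had 68.0 CPM in BT474, at least 259-fold higher with the blank set at 3 counts. The 259-fold figure rests on the value given to the blank. In GABRA3, miR-105-5p had 92.3 CPM in MDA-MB-468 and was not listed in BT474, at least 158-fold higher with the blank set at 3 counts, beside miR-767-5p in the same gene. The 158-fold figure too rests on the value given to the blank. A cluster of 8 hairpins in CLCN5 on chromosome X, with miR-532-5p (log2 2.23, 2.18 to 2.28) and miR-660-5p (2.82, 2.61 to 3.04), had 6 hairpins called higher in MDA-MB-468 and none lower. In GABRE, miR-224-5p (2.97) and miR-452-5p (3.97) were both higher in MDA-MB-468.

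Within the paralogs of the miR-17/92 cluster the ratios ranged widely. On chromosome X, miR-363-3p (log2 5.51, 5.29 to 5.74), miR-20b-5p (5.18, 4.73 to 5.67) and miR-106a-5p (3.77, 3.43 to 4.14) were called higher in MDA-MB-468, and so was miR-18b-5p, with 22 counts there and a blank in BT474 (log2 at least 1.72 with the blank set at 3 counts). The call of miR-18b-5p rests on an interval that took the blank as 0 counts. In the chromosome 13 cluster, miR-17-5p (2.69, 2.64 to 2.75) and miR-19a-3p (3.06, 2.55 to 3.61) were called higher in MDA-MB-468 and miR-92a-1-5p lower (-1.25, -1.86 to -0.64). In the MCM7 cluster on chromosome 7, miR-106b-5p stood at 0.07 (-0.01 to 0.14) and miR-25-3p at -1.18. No test of a difference between these clusters was run. From the chromosome 12 host MIR200CHG, miR-200c-3p (-1.35) and miR-141-3p (-1.50) were called higher in BT474, while miR-200c-5p (0.62, -0.34 to 1.68) and miR-141-5p (-0.72) were not called. Across 133 hairpins with both arms eligible, the log2 ratios of the 5p and 3p arms correlated with a Pearson coefficient of 0.84 and a Spearman coefficient of 0.79 and had the same sign in 104 (78.2%); hairpins are not independent replicates.

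On chromosome X, 26 of 43 hairpins were called higher in MDA-MB-468 and 7 lower (median log2 1.72, percentile 100 among matched random sets), and on chromosome 14 none of 19 was higher and 14 were lower (median -3.16, percentile 0.005). Chromosomes X and 14 were followed up among 22 examined, of which 5 lay in the outer 5%. With 1 value per cluster of hairpins within 50 kb the percentile was 100.00 for X and 0.08 for 14. For X the tables argue against a few co-transcribed clusters as the whole cause. On 14 the rule left mir-493 (start 100869060) and mir-379 (start 101022066), both of the imprinted C14MC cluster, as separate units. It therefore cannot decide the question for 14. Over hairpins listed in both libraries, 39 on X and 12 on 14, the percentile was 100.00 and 0.06 with medians of 1.80 and -2.17 (3 of 12 on 14 above 0), which argues against blanks set at 3 counts as the whole cause. A difference between the lines in copy number or in imprinted and X-linked transcription may underlie the pattern, a hypothesis that these data do not test.

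Over 63 pairs of neighbouring hairpins within 10 kb on the same strand, in 43 clusters, the median absolute difference of log2 ratios was 0.91. Among 10000 shuffles matched on expression the median was 2.11 and the lowest value 1.08. The ratios of neighbours correlated across pairs with a Pearson coefficient of 0.83 and a Spearman coefficient of 0.73, where pairs of 1 cluster are not independent. Only names listed on 1 precursor were used, but neighbours with different names can still share tags. How far shared tags account for the small difference was not tested.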
